A study of Mus musculus with 6 samples.

How the data were processed

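Ventricles of newborn mice were sampled at day 7 after sham surgery (n = 3) or apex resection (n = 3), and total RNA (6 ug per sample, biotin label) was hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds the authors' values, on a log2 scale as RMA gives and their range bears out, for 65450 probes and 6 arrays. RMA, which corrects background, normalizes by quantiles and summarises probes, is named in the submitters' processing notes, and its version, settings and genome build are not given in the sources used here. The deposited log2 values were used as they are, with no second normalization, and ran from 0.616 to 12.242. RMA gives values relative to the other arrays of the set and compresses changes of low signals, so folds of dim probes are understated. Array medians were 3.8576, 3.8734 and 3.8606 in sham and 3.903, 3.8931 and 3.882 in AR. The scale and centring past RMA are not stated. No scanner files were used here, so signal over background is not known probe by probe.

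Probes were named through the platform annotation, with symbols updated through the RefSeq gene table of assembly GRCm38.p6, which also gave the gene type. Of the probes, 30383 had 1 gene symbol, 2030 had several and 33037 had none here. A symbol was updated for 328 probes, the symbol of 30381 probes was found in the RefSeq table, and the probes covered 30046 symbols. No coordinates are printed, since the build of the annotation is not named. Probes whose mean over the 6 arrays lay below the 30th percentile of all probes were left out (quantile 0.3, a log2 value of 2.94), and a gene was represented by its probe with the highest mean. Probes with several symbols or none were left out of the fit by gene. They entered a separate count by probe, and those with none also entered the tests of neighbouring probes.

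Samples were grouped by their titles. The comparison, AR minus sham, was fitted over 23178 genes with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with no covariate, and p-values were adjusted by Benjamini-Hochberg at 0.05. Intervals are at 95% from the moderated error. Gene lists, 22 of pathways and 17 of cell types or tissues, were written before the data were examined, as were the test, the rule for named genes and the alternatives not named as added. They were tested with camera at a preset correlation of 0.01 and a minimum of 5 measured members, adjusted over the 39 lists, with camera at an estimated correlation and fry as alternatives. Counts adjusted over the list alone apply Benjamini-Hochberg to the limma p of the members of that list. Permutation tests and tests of neighbouring probes used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Neighbouring probes are those next to each other, or 2 places apart, in the order of the probe identifiers on the same chromosome, both with an SD over the arrays above 0.12.

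The rule for named genes took the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap and whose higher group mean was at or above the median probe mean (3.87), filled up by smallest p where fewer qualified, as for lncRNA genes. It added up to 4 members of each list, called members first and then by smallest p, the 5 largest rises and the 5 largest falls among lncRNA genes on the same conditions, and Mki67, Ccnb1, Cdk1, Myh6, Myh7, Nppa, Nppb, Col1a1 and Postn whatever their values. Of the members that the rule took from the lists, a part is given in the text. Uty, Kdm6a, Kdm5c, Eif2s3x and Aldh1a2 fall outside the rule and were chosen after their values were seen.

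The fit and the list test were tested on data simulated from the means of the 23178 genes, with spreads drawn from limma's fitted prior, for AR against sham, in 5 runs with 200 changed genes each. The fit recovered 86.8% of changes of 0.5 and 99.4% of changes of 1 on the log2 scale, 5.29% of its calls were false, and 0 had the wrong sign. A shift of 0.2 given to the mitosis list was recovered as 0.189 and passed in 5 of 5 runs, and other lists passed 0 times. The simulated genes vary independently, unlike real ones, and their spreads were drawn without regard to their changes. In the real data, 0 of the 10 genes with at least a 2-fold change at an unadjusted limma p under 0.05 were called. These include Xist and Y-linked messages, whose values differ widely between arrays of the same group. Of the 43 such genes with at least a 1.5-fold change, 5 were called. The recovered shares therefore do not carry over to the real arrays.

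Alternatives were no filter on low values, a filter at the 50th percentile, quantile normalization again, centring on the array median, eBayes with trend and robust, array weights, the mean of a gene's probes, the replicate number as a block, each array left out in turn, other thresholds, a plain equal-variance test and all probes together. Added after the data were seen were fry for the mitosis and DNA replication shifts, an adjusted p of 0.1, protein-coding genes alone, AR arrays 2 and 3 left out because Y-linked messages were found on them, and sham and AR interchanged for lncRNA genes.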

Results

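Expression was profiled in the ventricles of newborn mice at day 7 after surgery. In apex resection (AR in the sample titles), approximately 15% of the left ventricle is cut away at the apex, and sham-operated pups went through surgery without the resection. Before RNA was extracted, the apex was taken off the sham hearts and the scar off the AR hearts. The design text states an interest in proliferation over fibrosis and in long non-coding RNAs (lncRNAs) that act on cardiomyocyte proliferation. Each group held 3 biological replicates with 1 Affymetrix array each, and each array gave a log2 signal for 65450 probes. The array medians lay between 3.86 and 3.90. The Pearson correlation across probes, which are not independent replicates, was 0.9958 to 0.9969 within groups and 0.9922 to 0.9958 between them. The first principal component held 51.45% of the variance over genes and separated the groups, with sham arrays between -14.37 and -8 and AR arrays between 6.49 and 17.15. The number of arrays limits the precision of every value below.

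The sex-linked messages contradicted each other on 4 of the 6 arrays. Xist, the RNA that coats the silenced X chromosome of females, read 9.36 on sham array 1 and 9.49, 9.48 and 9.50 on the AR arrays, but 3.48 and 3.13 on sham arrays 2 and 3. The Y-linked messages Eif2s3y, Uty and Kdm5d read 5.49, 5.05 and 4.53 on AR array 2 and 5.65, 5.13 and 4.72 on AR array 3. On each of the other 4 arrays they lay between 1.99 and 2.69. Sham arrays 2 and 3 thus carried neither signal, and AR arrays 2 and 3 carried both. The X-linked gene Kdm6a, which escapes silencing in females, read 7.05, 7.06 and 7.18 on the sham arrays, 6.75 on AR array 1, and 6.24 and 6.28 on AR arrays 2 and 3. Kdm5c and Eif2s3x were also lowest on AR arrays 2 and 3. These protein-coding messages were thus lowest on the arrays with the Y-linked signal. By the protein-coding messages, 2 of the 3 AR arrays and 0 of the 3 sham arrays carried the male signal, so that in these rows the comparison of AR with sham is partly confounded with sex. Tsix, at 4.79 on sham arrays 2 and 3 and at 5.66 or above elsewhere, went with Xist. Neighbouring rows of the table split in a similar way. Over 792 pairs of adjacent probes, each of a protein-coding gene and a probe without a gene symbol, the mean correlation across the 6 arrays was -0.158 as labelled and 0.238 with the sham and AR columns interchanged on the unnamed side, the highest of the 720 column orders. Adjacent protein-coding probes correlated at 0.416 as labelled and adjacent unnamed probes at 0.387. For a single gene, an interchange of the groups turns the sign of the difference and leaves its size and p-value as they are. Camera sets a list against all other genes, so an interchange of only part of the rows would also change the p-values of lists. Lists with members in both parts would change in mean as well. The list tests were not run with such an interchange. Every direction below is therefore that of the arrays as labelled, and which rows carry the right labels was not settled.

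**Figure D1:**
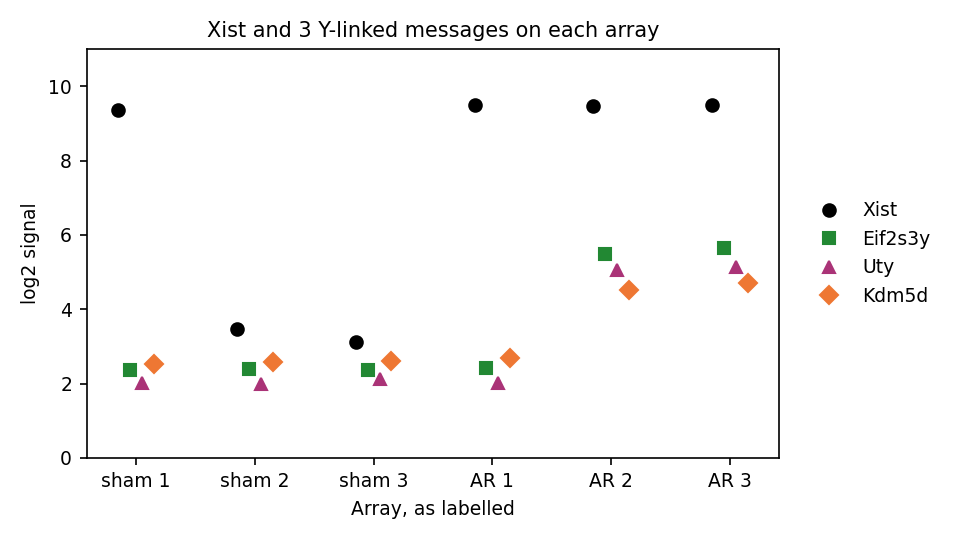
Log2 signal (vertical axis) of Xist and of the Y-linked messages Eif2s3y, Uty and Kdm5d on each of the 6 arrays as labelled (horizontal axis), 1 point per message and array. Xist is at 3.48 and 3.13 on sham arrays 2 and 3 and at 9.36 or above elsewhere, while the Y-linked messages are at 4.53 or above on AR arrays 2 and 3 and at 2.69 or below elsewhere.

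Among the genes that passed the test, Myl9, Apln and Csrp1 had some of the largest rises in the arrays labelled AR, and Asb14 the largest named fall. Myl9, a regulatory light chain of smooth muscle and non-muscle myosin, went from 8.95 ± 0.15 (SD, n = 3) in sham to 9.79 ± 0.13 (SD, n = 3) in AR. That is a rise of 0.84 ± 0.09 (SE) on the log2 scale, or 1.79-fold, with a limma adjusted p = 0.0385. Apln, the gene of the peptide hormone apelin, rose by 0.49 ± 0.05, and Csrp1, a LIM-domain protein of smooth muscle, by 0.48 ± 0.06. The homeobox gene Nkx2-3 rose by 0.43 ± 0.04, the beta-tubulin gene Tubb6 by 0.43 ± 0.06, and Ndn, the imprinted gene of necdin, by 0.42 ± 0.05. Among the falls, Asb14, an ankyrin repeat and SOCS box gene, changed by -0.75 ± 0.10, a 1.68-fold lower signal. The Rho GTPase-activating gene Arhgap20 changed by -0.51 ± 0.07, the zinc finger gene Zkscan3 by -0.51 ± 0.06, and Tnfsf10, the gene of the death ligand TRAIL, by -0.49 ± 0.07. Crebrf changed by -0.46 ± 0.06, Abca8a by -0.45 ± 0.06, the protocadherin Pcdh17 by -0.45 ± 0.04 and the junctional adhesion molecule Jam2 by -0.44 ± 0.05. The microRNA gene Mir1945 rose by 0.53 ± 0.08 and the pseudogene Vmn2r-ps16 by 0.38 ± 0.05. The snoRNA genes Gm22863, Gm23953, Gm24618 and Gm26332 each rose by 0.43 ± 0.06, with values identical on every array, so that they count as a single measurement. Lower in AR were the snRNA genes Gm25831, by -0.68 ± 0.06, and Gm24449, by -0.45 ± 0.04, and the pseudogenes Gm18852, by -0.65 ± 0.08, and Ifi203-ps, by -0.60 ± 0.08.

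These genes belong to 62 of 23178 genes that passed a Benjamini-Hochberg adjusted limma p of 0.05, with 28 higher and 34 lower in AR. The 4 snoRNA genes with identical values are each counted among the 62 and the 28. Protein-coding genes made up 20 of the rises and 24 of the falls. The changes of the 62 genes were small, between 0.28 and 0.84 in size on the log2 scale with a median of 1.31-fold, and 0 reached 2-fold. Their adjusted p lay between 0.0353 and 0.0494, and in all 62 the 3 AR values and the 3 sham values did not overlap. Another 10 genes, 9 higher and 1 lower, had at least a 2-fold change at an unadjusted limma p under 0.05 and were not called. Among the higher ones were the sex-linked Xist, Eif2s3y, Uty and Kdm5d, at 4.17, 2.15, 2.02 and 1.41, which contradicted each other between arrays. The atrial markers Nppa, Myl7 and Mybphl were among them too. Below the threshold the difference was broad: 6706 genes had an unadjusted p under 0.05, with 4199 higher and 2507 lower, where 1159 are expected by chance. The groups did not overlap in 8505 genes (36.69%, against 10% by chance). The balance of directions depended on the scaling: of 23178 genes, 13545 were higher in AR as deposited and 11358 with each array centred on its median. The count of calls was unstable: it was 0 with no filter on low values (7314 at an unadjusted limma p under 0.05) and 0 over all probes together (11622 unadjusted). By array, limma called 211 higher and 69 lower genes without sham replicate 1, 4 without AR replicate 1, and 0 without sham replicate 2 or 3 or AR replicate 2 or 3, where 4546 to 6608 genes still had an unadjusted p under 0.05, and it called 780 higher and 466 lower genes when protein-coding genes were fitted on their own. Without AR arrays 2 and 3 a single AR array is left, and the median size of the 62 genes was 0.42 against 0.39. Their direction could not turn there, because their groups did not overlap. With quantile normalization again limma called 36 higher and 96 lower genes, and with each array centred on its median 30 higher and 80 lower. An adjusted p of 0.1 gave 1675 higher and 1143 lower.

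**Figure D2:**
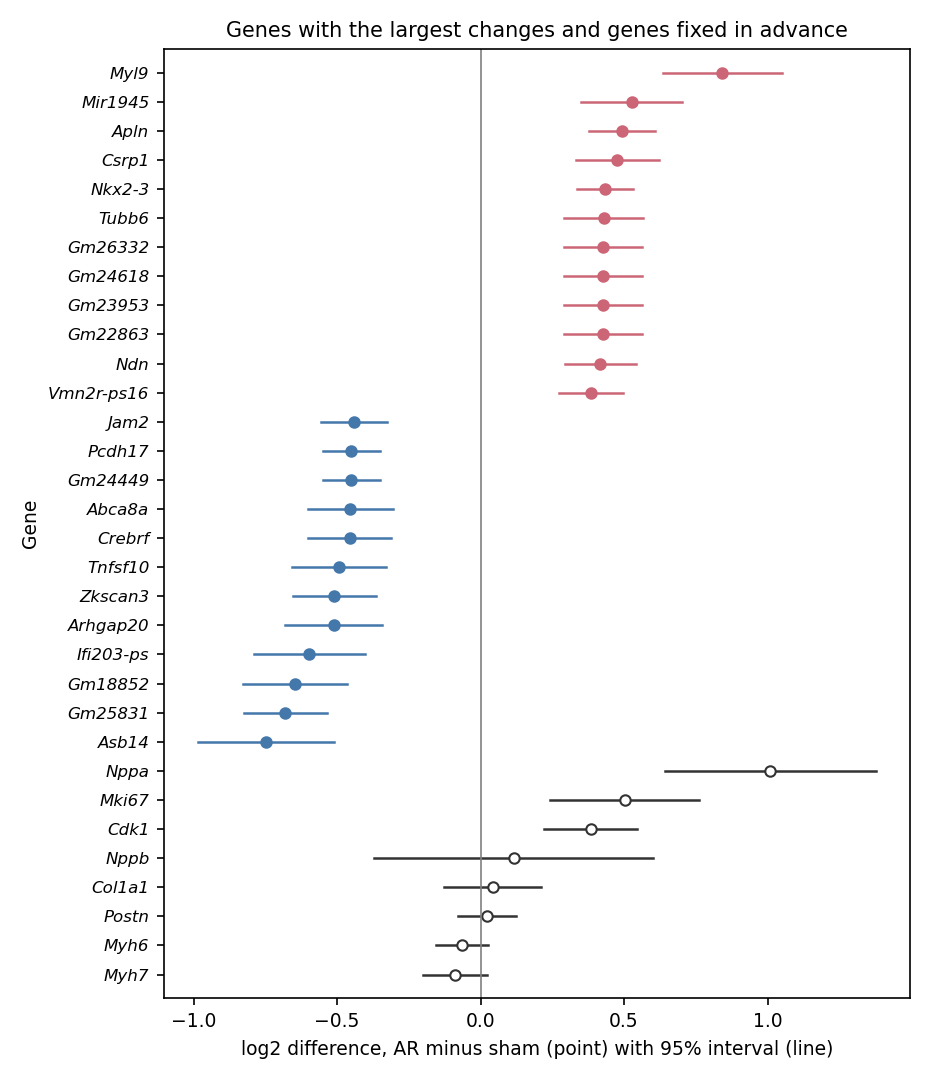
Difference in log2 signal, AR minus sham as labelled, with its 95% interval (horizontal axis), for the 12 largest rises, the 12 largest falls and the genes fixed in advance. Filled points passed the adjusted p of 0.05 over all genes and open points did not. Myl9 has the largest rise among the called genes, 0.84, and Asb14 the largest fall, -0.75.

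Genes of cell division were higher in the arrays labelled AR. All 32 measured members of the list for mitosis and the G2/M phase differed upward when adjusted over the list alone, and their mean difference was 0.43, or 1.35-fold. The list mean was 6.05 ± 0.19 (SD, n = 3) in sham and 6.48 ± 0.06 (SD, n = 3) in AR. The shift passed camera with a preset correlation (adjusted p = 6.08e-16, limma package), and not with an estimated correlation (adjusted p = 0.677). Over all genes tested, 0 members passed limma's adjusted p of 0.05, while 30 passed 0.1 and all 32 had an unadjusted p under 0.05. Mki67, whose protein marks cycling cells, differed by 0.50 ± 0.11 (limma adjusted p = 0.0703), and Cdk1, the kinase that drives entry into mitosis, by 0.38 ± 0.07 (limma adjusted p = 0.0645). Kif20a and Kif23, motors of the mitotic spindle and midbody, differed by 0.54 ± 0.10 and 0.45 ± 0.08, and Cdc20, an activator of the anaphase-promoting complex, by 0.43 ± 0.08. Cdca3, which acts at mitotic entry, differed by 0.38 ± 0.06. Ccnb1, also fixed in advance, had no probe with a single gene symbol and is not reported.

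The DNA replication and G1/S list moved in the same direction by less. Of its 32 measured members, 23 were higher when adjusted over the list alone, 0 were lower and 9 did not pass, and the mean difference was 0.25. Camera gave an adjusted p = 2.08e-09 with the preset correlation, and the adjusted p = 0.677 with an estimated correlation. By fry both this list and the mitosis list missed the threshold (adjusted p = 0.134). Tyms and Tk1, enzymes of thymidylate supply, differed by 0.32 ± 0.06 and 0.32 ± 0.06. Uhrf1, which maintains DNA methylation at replication, differed by 0.34 ± 0.08, and Mcm10, a replication initiation factor, by 0.26 ± 0.06. Over all genes tested 0 members passed limma's adjusted p of 0.05, and 26 had an unadjusted p under 0.05. Cell cycle inhibitors went both ways: 3 of 21 were higher and 5 lower when adjusted over the list alone, with a mean of -0.004 (camera adjusted p = 0.225). Cdkn2c and Cdkn2d, inhibitors of Cdk4 and Cdk6, differed by 0.26 ± 0.05 and 0.18 ± 0.05, and Rbl2 and Cdkn1b by -0.20 ± 0.04 and -0.20 ± 0.05. Without AR arrays 2 and 3, which carry the Y-linked signal, the mitosis and DNA replication means were 0.49 and 0.30. These means set AR array 1 alone against the sham arrays and hold no spread between AR hearts. Over all 6 arrays the atrial and epicardial markers were higher too, by 0.75 and 0.36 on average, and without AR arrays 2 and 3 by 1.27 and 0.52.

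**Figure D3:**
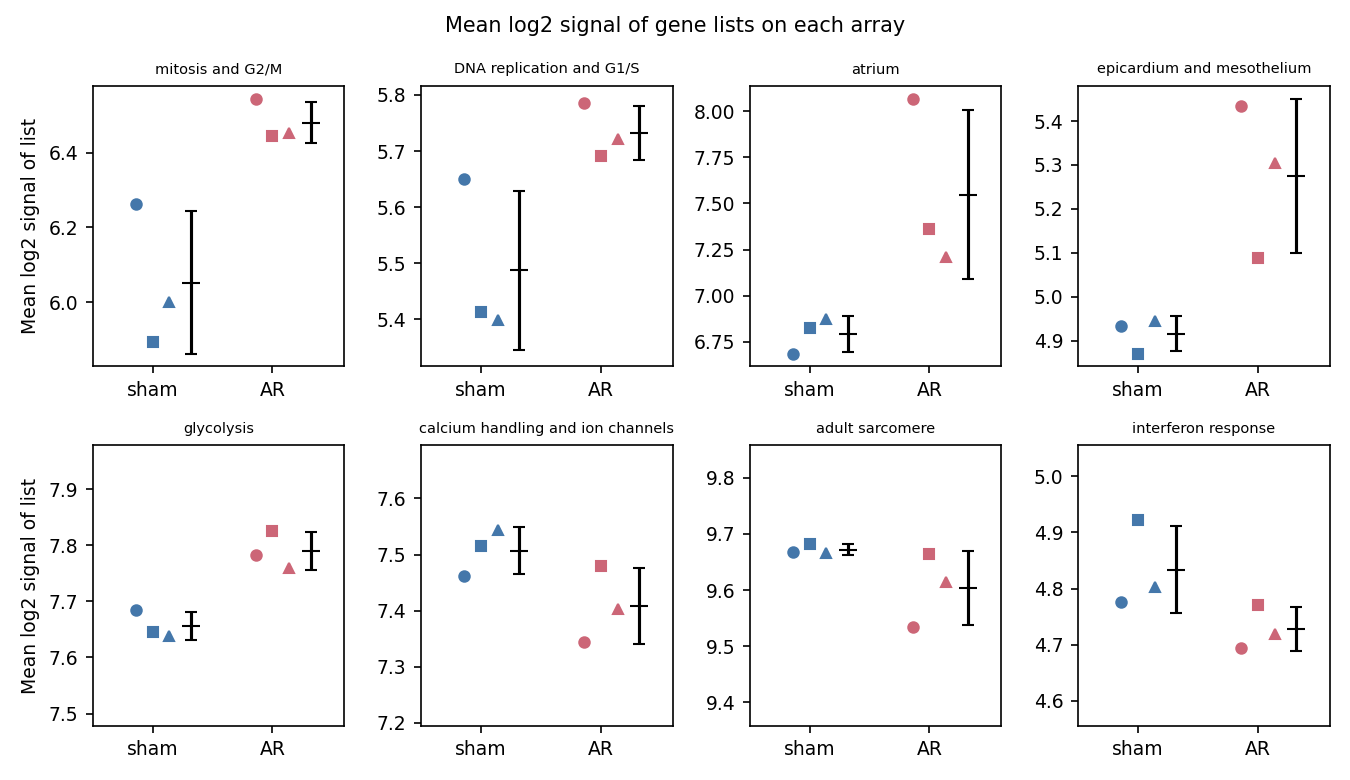
Mean log2 signal over the members of 8 gene lists (vertical axes, each with its own range) on the 3 sham and 3 AR arrays as labelled (horizontal axes). Circles, squares and triangles stand for replicates 1, 2 and 3, and the black bar for the mean ± SD of the group. In the mitosis panel the sham arrays reach 6.26 and the AR arrays start at 6.44. In the atrium panel AR array 1, at 8.07, lies above AR arrays 2 and 3 at 7.36 and 7.21.

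Markers of the atrium and of the heart's outer layer were higher in the arrays labelled AR, although the samples were ventricle. Of the 12 measured atrial markers, 9 were higher and 0 lower when adjusted over the list alone, with a mean difference of 0.75 or 1.68-fold (camera adjusted p = 0.000565, and adjusted p = 0.677 with an estimated correlation). Nppa, the gene of atrial natriuretic peptide, went from 10.46 ± 0.28 to 11.47 ± 0.25 (SD, n = 3 each), a difference of 1.01 ± 0.16 (limma adjusted p = 0.0555). Without AR replicate 1 the mean of the list was 0.49 (camera adjusted p = 0.000558). The atrial myosin light chain Myl7 differed by 1.12 ± 0.22, its counterpart Myl4 by 0.62 ± 0.11 and Mybphl by 1.03 ± 0.27. Epicardial and mesothelial markers were higher in 10 and lower in 1 of 12 cases when adjusted over the list alone, with a mean of 0.36 and Aldh1a2 as the lower member (camera adjusted p = 0.000458, and adjusted p = 0.677 with an estimated correlation). Msln differed by 0.64 ± 0.13, Gpm6a by 0.47 ± 0.10, Muc16 by 0.35 ± 0.07 and Wt1, a transcription factor of the epicardium, by 0.22 ± 0.05.

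Of the lists for other tissues, those of liver and skeletal muscle passed camera with the preset correlation. Liver markers had a mean difference of 0.30, with 7 of 8 higher when adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.677 with an estimated correlation). Their signals were low: the list mean in sham was 4.095, and 5 of the 8 had a sham mean at or above the median probe mean of 3.87. Ahsg, a plasma glycoprotein, differed by 0.55 ± 0.10 and Apoa1 by 0.31 ± 0.07. Skeletal muscle markers had a mean difference of 0.13, with 6 of 15 higher, 0 lower and 9 short of the threshold when adjusted over the list alone (camera adjusted p = 0.0086, and adjusted p = 0.677 with an estimated correlation), among them Tnnc2 at 0.24 ± 0.06. The skeletal muscle shift missed the threshold with quantile normalization again (adjusted p = 0.0541) and without sham replicate 2 (adjusted p = 0.0547), and the liver shift, at 0.15, without AR arrays 2 and 3 (adjusted p = 0.0738). The 5 sex-linked messages tested were all higher when adjusted over the list alone, with a mean of 2.08 (camera adjusted p = 0.0243, and adjusted p = 0.677 with an estimated correlation), and with the non-coding Xist and Tsix turned, 2 of them are lower and the mean is 0.15. The shift missed the threshold without AR arrays 2 and 3 (mean 0.996, adjusted p = 0.504) and without sham replicate 2 or AR replicate 2 or 3 (adjusted p = 0.088, 0.0519 and 0.0767).

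Glycolysis genes were higher in the arrays labelled AR, and 4 lists had means below 0 with few members past the test. Of 20 glycolysis genes, 10 were higher and 0 lower when adjusted over the list alone, with a mean of 0.13 (camera adjusted p = 0.00178, and adjusted p = 0.677 with an estimated correlation). The lactate exporter Slc16a3 differed by 0.42 ± 0.07, the glycolytic enzyme Pgk1 by 0.34 ± 0.07 and the glucose transporter Slc2a1 by 0.28 ± 0.05. Without AR arrays 2 and 3 the shift missed the threshold (0.13, camera adjusted p = 0.0892). The calcium handling and ion channel list shifted by -0.10 (camera adjusted p = 0.00321, and adjusted p = 0.677 with an estimated correlation), with 3 of 24 lower when adjusted over the list alone. The potassium channel genes Kcnd2 and Kcnj8 differed by -0.56 ± 0.12 and -0.29 ± 0.06, and Ryr2, the calcium release channel, by -0.28 ± 0.07. The adult sarcomere list shifted by -0.07 (camera adjusted p = 0.0113, and adjusted p = 0.677 with an estimated correlation), with 2 of 21 lower when adjusted over the list alone. Lmod2, which sets the length of thin filaments, changed by -0.355 ± 0.04 and was the only member of the 39 lists past the threshold over all genes (limma adjusted p = 0.0366). Fatty acid oxidation shifted by -0.05 (camera adjusted p = 0.0156, and adjusted p = 0.751 with an estimated correlation), with 0 of 26 past the threshold over the list alone and 2 at an unadjusted limma p under 0.05. That mean was 0.0015 without AR replicate 1 and -0.0097 without sham replicate 2 (camera adjusted p = 0.389 and 0.243). The sarcomere mean was -0.03 without AR replicate 1 (camera adjusted p = 0.144), and with quantile normalization again the calcium, sarcomere and fatty acid shifts missed the threshold (camera adjusted p = 0.0507, 0.249 and 0.217). With array weights the sarcomere and fatty acid shifts missed it as well (-0.05 and -0.0017, camera adjusted p = 0.0682 and 0.32). Without AR arrays 2 and 3 the calcium, sarcomere and fatty acid means were -0.16, -0.14 and -0.15. These means rest on AR array 1 alone, the array without which the sarcomere and fatty acid means were -0.03 and 0.0015. Interferon response genes shifted by -0.11 (camera adjusted p = 0.00321, and adjusted p = 0.677 with an estimated correlation), with 3 of 21 lower when adjusted over the list alone, and the sensor gene Ifih1 differed by -0.30 ± 0.06. Without sham replicate 2 the interferon mean was -0.06 (camera adjusted p = 0.0803).

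The collagen, periostin, B-type natriuretic peptide and myosin heavy chain genes fixed in advance did not pass the test, while single members of the matrix and fetal lists passed over their list. Col1a1, a fibrillar collagen, differed by 0.04 ± 0.07 (limma adjusted p = 0.72) and Postn, periostin, by 0.02 ± 0.04 (limma adjusted p = 0.752). Nppb, the gene of B-type natriuretic peptide, differed by 0.12 ± 0.21 (limma adjusted p = 0.731). The myosin heavy chains Myh6 and Myh7 differed by -0.06 ± 0.04 and -0.09 ± 0.05 (limma adjusted p = 0.307 and 0.247), and the groups did not overlap for Myh6. The direction of Nppb, Col1a1 and Postn turned with array weights, with centring or without 1 array. The extracellular matrix list, with a mean of 0.11 (camera adjusted p = 0.284), had 6 of 28 members higher and 2 lower when adjusted over the list alone. Tnc, tenascin C of the injury matrix, differed by 0.65 ± 0.12 and the crosslinking enzyme gene Lox by 0.53 ± 0.13, while Dcn, decorin, differed by -0.26 ± 0.05. The fetal cardiac programme had a mean of 0.23 and a median of 0.06 (camera adjusted p = 0.115), with 7 of 22 higher and 1 lower over the list alone. Of its members 9 stand in another list, among them the atrial markers Nppa, Myl4, Myl7 and Mybphl. Acta1, skeletal alpha-actin, differed by 0.60 ± 0.12.

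The other lists also stayed short of the camera threshold of 0.05. The mean difference was -0.06 for the circadian clock (adjusted p = 0.0544), 0.10 for the Wnt pathway (adjusted p = 0.0544), 0.13 for heart growth factors and receptors (adjusted p = 0.365) and -0.02 for oxidative phosphorylation (adjusted p = 0.225). It was -0.03 for cardiac transcription factors (adjusted p = 0.123), 0.07 for ribosome biogenesis (adjusted p = 0.138), 0.06 for the hypoxia response (adjusted p = 0.709) and 0.01 for YAP and Hippo targets, with a sign that turned under another scaling (adjusted p = 0.732). Inflammatory cytokines and chemokines gave 0.04 (adjusted p = 0.68), immediate early genes 0.02, with a sign that turned with the scaling (adjusted p = 0.904), and the heat shock and unfolded protein response 0.04 (adjusted p = 0.851). Among cell types, cardiomyocyte markers had a mean of 0.02 and a median of -0.03 (adjusted p = 0.138), endothelial markers a mean of 0.03 and a median of -0.09 (adjusted p = 0.126), and fibroblast markers a mean of -0.01 (adjusted p = 0.225); the sign of the cardiomyocyte and fibroblast means turned with the scaling. The mean was 0.03 for smooth muscle and pericyte markers (adjusted p = 0.51), -0.02 for macrophages and monocytes (adjusted p = 0.321), 0.03 for neutrophils, with a sign that turned with the scaling (adjusted p = 0.51), 0.08 for T, B and NK cells (adjusted p = 0.393) and -0.05 for the thymus (adjusted p = 0.467). It was 0.15 for erythroid cells (adjusted p = 0.393), 0.22 for adipocytes (adjusted p = 0.29), 0.10 for the lung (adjusted p = 0.0686) and 0.11 for nerve and Schwann cells (adjusted p = 0.0829).

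Few lncRNA genes passed the test. Of 2142 measured lncRNA genes, 3 were called, all lower in the arrays labelled AR: Gm11529 by -0.38 ± 0.05, 4930473H19Rik by -0.32 ± 0.04 and Gm21411 by -0.31 ± 0.04, with limma adjusted p between 0.0483 and 0.0494. At an unadjusted limma p under 0.05 there were 216 higher and 316 lower lncRNA genes, and at an adjusted p of 0.1 there were 80 and 115. Below the threshold, the rule for named genes took Gm19277, at 0.99 ± 0.15 (limma adjusted p = 0.0535), Gm20300 at 0.37 ± 0.05, Gm12002 at 0.57 ± 0.10, Gm12519 at 0.50 ± 0.10 and Gm14221 at 0.38 ± 0.07, with Gm4577 at -0.25 ± 0.04 and 2610020C07Rik at -0.29 ± 0.05 on the other side. The list of lncRNAs with established names had a mean of 0.02, whose sign turned with the scaling (camera adjusted p = 0.904), with 3 of 25 higher and 2 lower when adjusted over the list alone. Airn, the antisense transcript of the Igf2r locus, differed by 0.26 ± 0.06 and Ftx, from the X-inactivation centre, by 0.20 ± 0.05. Without sham replicate 2 or 3, or any AR replicate, limma called 0 lncRNA genes, with 390 to 506 at an unadjusted p under 0.05. Without sham replicate 1 it called 8, of which 5 were higher and 3 lower in AR. With sham and AR interchanged for lncRNA genes, as the sex-linked messages leave open, the 3 calls of the fit to all arrays are higher in AR.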

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

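The tests of neighbouring probes 2 places apart, of the splits of the arrays for gene lists and for the mitosis and replication shifts, and of the mitosis list against the atrial and epicardial lists were written down before their results were seen; the other tests of this part were chosen after.

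Probes without a gene symbol, which the comparisons of genes leave out, also held calls. Of 20927 such probes, 5901 had an unadjusted limma p under 0.05 and 235 passed an adjusted limma p of 0.05 within their class, 152 higher and 83 lower in the arrays labelled AR (83 higher and 152 lower if the groups are interchanged in these rows), with a median size of 0.461 on the log2 scale. In the same fit 0 of 23386 probes with 1 gene symbol passed within their class (smallest adjusted p = 0.114, 5361 unadjusted), against the 62 genes called when genes were fitted on their own, and the classes were not tested against each other. Over all 45815 probes limma called 0, with 11622 at an unadjusted p under 0.05.

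Xist and the Y-linked messages disagreed on 4 of the 6 arrays, 2 low in both and 2 high in both. Arrays under a wrong label as a whole would keep all rows of an array together, so these 4 arrays argue against that. Hearts of both sexes pooled on an array could give both signals, but not neither: on the arrays low in Xist the Y-linked messages lay 0.003 above those of the arrays high in Xist alone, which argues against pooling as the whole cause. A candidate explanation that stays open is that sham and AR columns are interchanged for part of the rows. With that interchange 727 pairs of protein-coding and unnamed probes 2 places apart correlated at 0.157, the highest of 720 column orders, and at -0.103 as labelled. Xist would then read 9.36, 3.48 and 3.13 on AR arrays 1, 2 and 3, low only where the Y-linked messages are high. Tsix would follow it, so that each array would carry the signal of a single sex. Which rows carry the right labels stays open. Rows of lncRNA genes correlated with unnamed probes 1 and 2 places away at 0.134 and 0.084 as labelled and 0.013 and 0.009 interchanged, and with protein-coding probes 2 places away at -0.002 and 0.156, so 3 of the 4 comparisons put them with the unnamed rows, while protein-coding probes 1 place away, at 0.167 and 0.072, do not; no biological explanation was tested.

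Atrial markers were higher in the arrays labelled AR by 0.75 on average. A return of the fetal ventricular programme as the whole cause is argued against by Myh7, whose difference has an upper 95% limit of 0.0215 where at least 0.5 was required, although the upper limit for Nppb is 0.60 and Acta1 was higher by 0.60. More atrial tissue in the AR samples may account for the pattern: the deviations of the 12 markers from their group means had a mean pairwise correlation of 0.72, which 0 of 10000 random lists of matched expression reached. A response of the markers that varies between hearts would give the same correlation, so an effect of the resection itself stays open. Of the 12 markers 8 stand in another list as well, and 12 had a sham mean at or above the median probe.

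The mitosis and DNA replication lists were higher in the arrays labelled AR. A shift of all genes of that expression level is argued against, since 0 of 10000 random lists of matched expression reached the mean of 0.43 of the mitosis list, and the highest of them had 0.17. Atrial or epicardial tissue carried over cannot be told apart from the groups with 6 arrays: the deviations of the mitosis list correlated with those of the atrial list at r = 0.093 (Spearman's rho = -0.086, permutation p = 0.611 and 0.917) and with those of the epicardial list at r = 0.359 (rho = 0.314, permutation p = 0.194 and 0.5), and without the 2 arrays farthest from the median r was -0.465 and 0.526. The effect of the resection stays open beside it. A difference between the sexes was not tested: by the protein-coding messages, AR arrays 2 and 3 alone carried the male signal. AR array 1, without that signal, also lay above the sham arrays, with means of 6.55 for mitosis and 5.79 for DNA replication. Both lists would be lower in AR if sham and AR were interchanged in the protein-coding rows.

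With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 62 genes and the highest other 0, and for lncRNA genes 3 and 0, so that no other split was as large in either case. The real split shifted 12 lists where the highest other shifted 14, and 3 of 10 splits, the real one included, shifted at least as many. The mitosis list shifted by 0.43 against 0.31 in the highest other split, and the DNA replication list by 0.25 against 0.22.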

How the results depend on the processing

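The adjusted p of 0.1, protein-coding genes alone, fry for the mitosis and DNA replication shifts, the exclusion of AR arrays 2 and 3 and the interchange for lncRNA genes were chosen after the data were seen. The count of 62 called genes became 0 with no filter on low values (7314 at an unadjusted limma p under 0.05), 119 with the 50th percentile filter, 132 with quantile normalization again, 110 with centring on the median, 128 with trend and robust and 290 with array weights. It was 10 at an unadjusted p under 0.05 with a 2-fold change, 2818 at an adjusted p of 0.1, 1 by the plain equal-variance test, 0 over all probes (11622 unadjusted), 1246 over protein-coding genes alone, and 0 without AR arrays 2 and 3 (5979 unadjusted), where the lone AR array was assumed to vary like the sham arrays. Leaving out 1 array gave 0 to 280 calls. The 62 called genes were all among those called with centring, trend and robust, array weights and the block, and 59 of them with quantile normalization. For lncRNA genes the count of 3 became 0 with no filter (623 unadjusted), 6 with the 50th percentile filter, 11 with quantile normalization, 6 with centring, 5 with trend and robust, 25 with array weights, 195 at an adjusted p of 0.1, 5 at an unadjusted p under 0.05 with a 1.5-fold change and 0 without AR arrays 2 and 3 (322 unadjusted). Leaving out 1 array gave 0 to 8. Apart from the smaller numbers of arrays and the changed sets of genes, the cause was not tested.

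The replicate numbers were not shown to pair the arrays: same-numbered arrays deviated together with correlations of 0.084, 0.07 and 0.101, although each array correlated best with its own number (highest other 0.022), a hint from the data and not the design. With the replicate number as a block, 536 genes and 29 lncRNA genes were called, and the 12 lists and the mitosis and DNA replication shifts passed as before.

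The 12 shifted lists became 0 with an estimated correlation (0 unadjusted) and 0 with fry (14 unadjusted), and were 8 to 16 under the other settings. The mitosis shift of 0.43 and the DNA replication shift of 0.25 kept their direction under every setting run. Leaving out or weighting arrays could not turn it, since the list means of the groups did not overlap. Mitosis means reached 6.26 in sham and started at 6.44 in AR, and DNA replication means reached 5.65 and started at 5.69. A change of test leaves the means as they are. An interchange of sham and AR in these rows would turn both shifts and was not among the settings. They lost the threshold with an estimated correlation, at 0.43 and 0.25 with an adjusted p = 0.677, because that setting replaces 0.01 by estimates of 0.905 and 0.748. They lost it by fry as well, at 0.43 and 0.25 with an adjusted p = 0.134. Under the other settings their adjusted p was at most 1.08e-05, and leaving out 1 array gave 0.35 to 0.54 and 0.20 to 0.33.

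Among named genes that were not called, the sign turned for Postn with centring (-0.0062) and array weights (-0.0014), for Nppb with array weights (-0.0764) and for Alas2 with array weights (-0.1631). Leaving out 1 array gave -0.0077 to 0.0408 for Postn, -0.0116 to 0.1151 for Col1a1, -0.0498 to 0.3397 for Nppb, -0.1055 to 0.3006 for Alas2 and -0.2549 to 0.0138 for Cd8b1. The 28 named genes that were called kept their direction under every setting run on them. Where arrays were left out this was fixed in advance, since the groups of these genes did not overlap. All 28 lost the threshold with no filter, without sham replicate 2 or 3 and without each AR replicate. Signal over background, which limits dim probes, is not known here.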

Other observations

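The gene families below were chosen after the data were seen. Replication-dependent histone genes, which package new DNA, had a median difference of 0.26 between the arrays labelled AR and sham, and 13 of 21 were higher and 1 lower when adjusted over the family alone (camera adjusted p = 0.000146, and adjusted p = 0.296 with an estimated correlation). Tubulin genes had a median of 0.25, with 12 of 16 higher and 0 lower (camera adjusted p = 2.01e-07, and adjusted p = 0.235 with an estimated correlation; 13 higher at an unadjusted limma p under 0.05 and 0 lower). These families kept their direction under quantile normalization and under centring on the array median.

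The medians of the small RNA classes lay on both sides of 0. Of 490 snRNA genes, copies of the spliceosomal RNAs, 71 were lower and 0 higher when adjusted over the family alone, with a median of -0.128 (camera adjusted p = 6.13e-25, and adjusted p = 0.228 with an estimated correlation), and at an unadjusted limma p under 0.05 there were 209 lower and 8 higher. Each copy was counted as a separate gene, and whether copies share values was not examined in this family. Among 9 let-7 microRNA genes 6 were lower and 1 higher over the family alone, with a median of -0.19 (camera adjusted p = 0.00384, and adjusted p = 0.228 with an estimated correlation). The 557 snoRNA genes had a median of -0.01, with 15 higher and 8 lower over the class alone, and the 382 miRNA genes a median of 0.02, with 15 higher and 15 lower. The snRNA and let-7 genes kept their direction under quantile normalization and centring. Their direction relative to the protein-coding genes is not settled by the labels, and the pattern of the lncRNA rows does not carry over to them. Small RNA rows correlated with unnamed probes 1 and 2 places away at 0.004 and -0.024 as labelled and 0.072 and 0.068 interchanged. With protein-coding probes 1 and 2 places away they correlated at 0.019 and -0.001 as labelled and 0.046 and -0.017 interchanged.

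Single arrays stood out for genes of other tissues, chosen here after their values were seen. Bmp10, a growth factor of the atrium, read 9.64 on AR array 1, 5.22 and 6.34 on the other two AR arrays, and 3.98, 5.14 and 4.25 on the sham arrays. Ucp1, the uncoupling protein of brown fat, read 7.37 on AR array 2 and 5.09 and 3.55 on the other two, against 3.53, 4.23 and 4.55 in sham.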
